A study of Mus musculus with 9 samples.

How the data were processed

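The series holds RNA sequencing of islets of Langerhans from 12-week-old mice, with 3 libraries each of wild type, db/+ and db/db, all with the same strain label. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with a Ribo-Zero Gold ribosomal RNA removal kit, and sequencing was done on a HiSeq 2500. Per the submitters' processing notes, reads were converted with bcl2fastq 2.20.0.422 and aligned with TopHat2 2.0.14 to the mm10 genome. The deposited values are read counts per gene symbol in 1 table, which the authors gave without normalisation; the values are whole numbers with library totals between 8860024 and 11734886. The program, annotation and strand setting used for counting are not given in the sources used here, so overlapping and antisense genes, and near-identical copies such as the trypsinogens, Ins1 and Ins2, or H2-K1 and H2-D1, can share counts.

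The table has 52459 gene symbols, 29854 of them with a count above 0 in the libraries used. It has 1 column that matches no sample of the series, which was not used. Total counts were 11473420, 10806499 and 9558955 in WT, 11691114, 11164775 and 11734886 in db/+, and 8860024, 9260105 and 9212526 in db/db. A total of 3 counts in a library, the limit that a count of 0 allows, is 0.238 to 0.412 CPM. Gene positions are those of the RefSeq annotation of GRCm38, the assembly of mm10, in which 87.7% of tested symbols were found. Pearson correlations of log2 CPM within groups were 0.982 to 0.985 in WT, 0.985 to 0.987 in db/+ and 0.968 to 0.984 in db/db.

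Genes were kept by filterByExpr on the 3 groups, leaving 16826. Counts were normalised with TMM factors, and a model with a term for each group was fitted to all 9 libraries with edgeR 4.0.16 in R 4.3.3 (robust dispersion estimates, common biological coefficient of variation 0.129, 6 residual degrees of freedom). Each pair of groups was compared by the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. CPM were computed from TMM-normalised library sizes. A total of 34 lists of marker and pathway genes with at least 5 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry. A list of adipocyte markers had 4 tested members and took part in no set test. Members of each list were counted with adjustment over all genes and over the list alone.

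The design, the lists and the rule for named genes were fixed before the data were examined. The rule names Lepr, Ins1, Ins2, Gcg, Sst, Ppy and Iapp in every comparison, sex-linked genes as a library check, and from each described list the 2 risen and 2 fallen members with the smallest adjusted p. It also names the 10 highest and 10 lowest fold changes of each db/db comparison, and 5 and 5 for db/+ against WT. Those are taken among genes past the threshold with at least 10 CPM in the higher group and no overlap between groups, leaving out predicted genes, small RNAs and pseudogenes that their symbols show as such. Some genes that the rule names are not reported here.

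The tests were run first on simulated counts with 200 changed genes, 100 at 1.5-fold and 100 at 3-fold. In the db/db against WT simulation on 16557 genes, 43% and 74% were recovered at 1.5-fold and 3-fold, and 11.4% of calls were false, above the nominal 5%. For db/db against db/+ (16641 genes) 35% and 80% were recovered with 4.96% false, and for db/+ against WT (16573 genes) 41% and 79% with 5.51% false.

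Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors or library totals in place of TMM, no low-count filter or CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, non-robust dispersion, only the 2 compared groups in the fit, and a test against a 1.5-fold change. Further ones were the first letter of the sample title or the mean log2 CPM of acinar genes as a covariate, removal of acinar genes, and each library left out. The acinar mean, which took in trypsinogen genes, was higher in every db/db library than in any other, so this covariate partly follows genotype. A covariate of summed Y-linked CPM, removal of ribosomal RNA genes, and a per-library correction for transcript length were added after seeing the data. Transcript lengths came from a mouse annotation of another assembly, used for lengths only, and 87.2% of tested genes had one. Replicate numbers follow the order of the samples and pair nothing. Figures were drawn with matplotlib 3.10.9.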

Results

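RNA sequencing counts were analysed for 9 libraries of mouse islets of Langerhans, the clusters of hormone-secreting cells of the pancreas, taken at 12 weeks of age. The groups were wild type (WT), db/+ and db/db, with 3 libraries each. The db allele is a mutant form of Lepr, which encodes the leptin receptor, and db/db mice are a widely used model of obesity and diabetes. Total counts ranged from 8860024 to 11734886 per library, and 16826 genes were tested. Levels are given as CPM, counts scaled to the normalised library size, as mean ± SD with n = 3 per group, and fold changes on the log2 scale ± SE. Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless camera is named. The labels do not say whether each library came from a separate animal, so the p values measure only the spread between these libraries. A total of 3 counts corresponds to between 0.238 and 0.412 CPM in these libraries, which covers counting error only.

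The targeted gene Lepr (chromosome 4, 101717137 to 101815352, mm10) was low in every library. It stood at 3.17, 1.72 and 1.93 CPM in WT, 4.37, 1.52 and 1.63 CPM in db/+, and 9.47, 2.60 and 2.05 CPM in db/db. The differences did not pass the test, with a log2 fold change of 1.0 ± 0.65 (adjusted p = 0.245) for db/db against WT and 0.13 ± 0.65 (adjusted p = 0.957) for db/+ against WT. The db mutation changes how a Lepr transcript is spliced, so a count over the whole gene does not check the genotype labels.

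Sex-linked genes differed between the groups. Xist, the RNA of the inactive X chromosome, was at 565, 0.722 and 596 CPM in WT, at 0.506 CPM or less in db/+, and at 308, 948 and 858 CPM in db/db. The sum of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty) was 219, 342 and 235 CPM in WT, 417, 373 and 407 CPM in db/+, and 176, 1.11 and 0.108 CPM in db/db. The libraries WT 1, WT 3 and db/db 1 thus held both Xist and Y-linked counts, which a single mouse would not ordinarily give. These libraries may therefore hold islets of mice of both sexes, unlike the others. The labels do not give the sex of the mice or say whether islets were pooled. Gm42418 and Lars2, whose loci overlap ribosomal RNA sequence so that their counts are uncertain, together took 17.9%, 13.3% and 0.0558% of db/db counts, 1.89% to 2.58% of WT counts and at most 0.0237% of db/+ counts. The acinar enzyme gene Cpa1 was at 1290, 721 and 626 CPM in WT, 1593, 2129 and 3746 CPM in db/+, and 5579, 1857 and 2017 CPM in db/db. The first principal component held 60.9% of the variance and set the db/db libraries apart from the other 6.

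**Figure D1:**
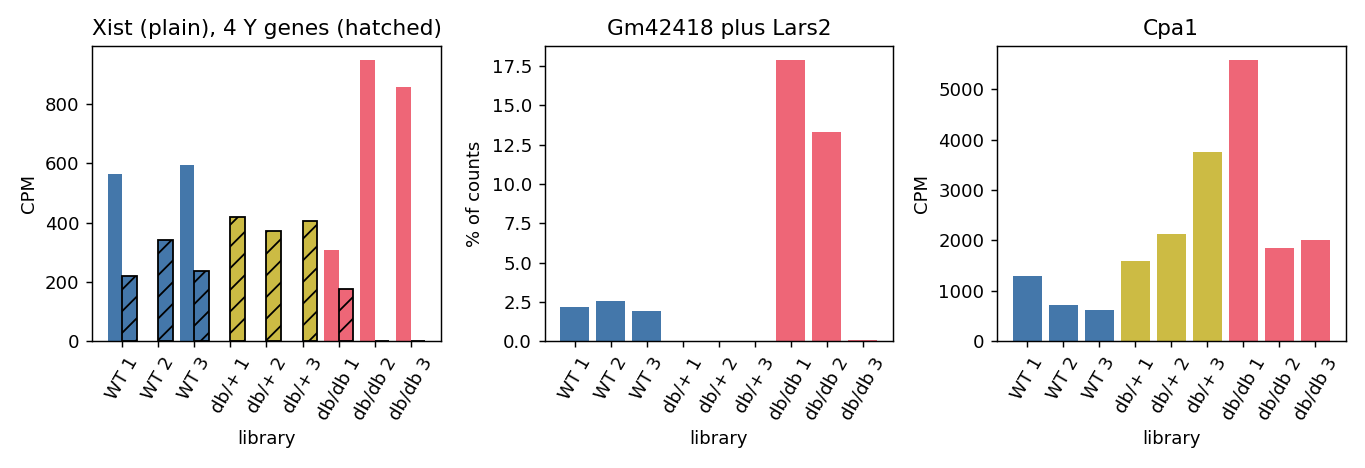
Left, Xist (plain bars) and the sum of 4 Y-linked genes (hatched bars) per library in CPM; middle, Gm42418 plus Lars2 as a percent of counts; right, Cpa1 in CPM. Blue is WT, yellow db/+ and red db/db, and the 3 db/+ libraries have Y-linked counts with at most 0.506 CPM of Xist.

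The comparison of db/db with WT islets asks what differs in islets of diabetic mice. The insulin genes were abundant in both groups and did not pass the test. Ins2 stood at 51590 ± 5264 CPM in db/db and 50306 ± 10887 CPM in WT, and Ins1 at 25482 ± 9711 and 35360 ± 7891 CPM (log2 fold change -0.47 ± 0.29, adjusted p = 0.235). Lower levels were found for 2 transporter genes of beta cells. Slc2a2, the main glucose transporter of mouse beta cells, fell from 1184 ± 137 to 157 ± 75.5 CPM, and Slc30a8, the zinc transporter of insulin granules, from 1356 ± 82.3 to 259 ± 75.2 CPM. Both were chosen after their values were seen. Iapp, which encodes the amyloid peptide secreted with insulin, rose from 14196 ± 1446 to 33673 ± 3834 CPM, and Aldh1a3, a retinaldehyde dehydrogenase, from 2.40 ± 0.622 to 496 ± 91.3 CPM.

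Of 16826 tested genes, 7018 changed, 3670 higher and 3348 lower in db/db, and 1549 and 703 of them by at least 2-fold. The glucagon gene Gcg fell by 0.81 ± 0.19 (adjusted p = 0.00625), while Sst (0.03 ± 0.11, adjusted p = 0.825) and Ppy (-0.35 ± 0.14, adjusted p = 0.0571, from 0.0147 to 0.198 with a library left out) did not pass. Among genes with at least 10 CPM in the higher group and no overlap between the groups, the 10 with the highest fold changes were Prss1, Cck, Prss3, Aldh1a3, Ros1, Csn3, Reg3g, C1qtnf1, Gast and Bcat1. Cck and Gast, peptide hormone genes not typical of adult beta cells, reached 66.5 ± 45.4 and 10.6 ± 4.03 CPM against means of 0.0866 and 0.121 CPM in WT. Cck was at 35.6 and 45.4 CPM in db/db 2 and db/db 3, and its mean rests largely on db/db 1 (118.7 CPM), which also held the most acinar counts. The receptor kinase gene Ros1 reached 26.2 ± 4.57 CPM, the casein gene Csn3 18.0 ± 5.20, the antimicrobial lectin gene Reg3g 11.1 ± 1.05 and the aminotransferase gene Bcat1 25.6 ± 5.66, each with a WT mean of 0.482 CPM or less. C1qtnf1 rose by 6.73 ± 0.25 to 165 ± 26.9 CPM. The 10 lowest fold changes belonged to Kcnj12 (-5.70), Trpm5 (-5.24), Cox6a2 (-5.05), the gene listed as T2 (-4.80), Npas4 (-4.72), Kcng3 (-3.95), Cdh7 (-3.92), Fam151a (-3.74), Nnat (-3.71) and Vwa5b1 (-3.69), with SE from 0.13 to 0.47. Trpm5, a cation channel gene, went from 127 ± 16.2 to 3.32 ± 2.25 CPM, and Npas4, a transcription factor gene induced by activity, from 259 ± 25.1 to 9.79 ± 1.43 CPM.

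**Figure D2:**
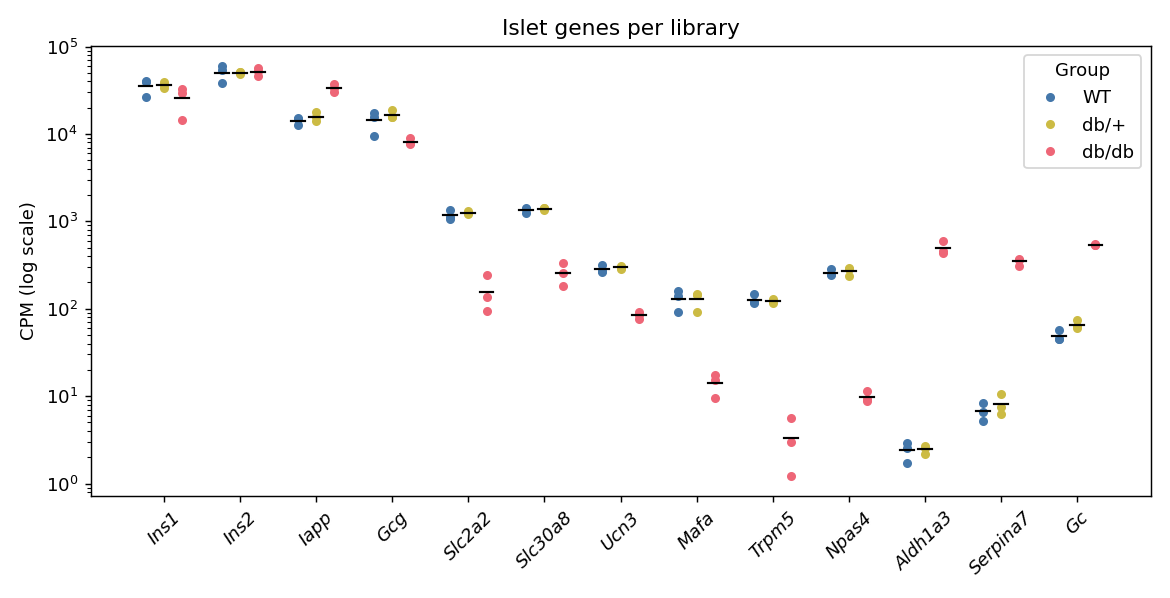
Level of 13 islet genes in each library, in CPM on a log axis, with points for libraries and a short line for the group mean. Slc2a2, Slc30a8, Ucn3, Mafa, Trpm5 and Npas4 are lower in all 3 db/db libraries than in any WT or db/+ library, and Iapp, Aldh1a3, Serpina7 and Gc are higher.

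Within the list of glucose sensing and insulin secretion, 20 of 28 tested members fell, 2 rose and 6 did not pass, with the same counts adjusted over the list alone. The fallen members included the incretin receptor gene Gipr (-2.01 ± 0.09, adjusted p = 3.68e-09) and Ucn3, a peptide of mature beta cells (-1.75 ± 0.10, adjusted p = 1.46e-08). The risen ones were the prohormone-processing enzyme gene Cpe (0.51 ± 0.10, adjusted p = 9.49e-04) and Syt7 (0.24 ± 0.09, adjusted p = 0.0470). The Syt7 call ended without WT 1, WT 2, db/+ 2, db/+ 3, db/db 2 or db/db 3, with adjusted p from 0.0246 to 0.225 over the left-out libraries. Camera gave the list an adjusted p of 1.28e-14, and adjusted p = 0.197 with an estimated correlation. Without db/db 1, which held both Xist and Y-linked counts, 17 members fell, and with acinar content as a covariate 10 members of the list glucose sensing and insulin secretion fell. Of the 16 tested beta cell transcription factors, 9 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.00691, and adjusted p = 0.592 with an estimated correlation). Pdx1 (-1.02 ± 0.08) and Neurod1 (-1.03 ± 0.09), both regulators of insulin transcription, fell, and Bach2 (2.25 ± 0.23) and Rfx6 (0.74 ± 0.08) rose. The counts of beta cell transcription factors without db/db 1 were 9 fallen and 4 risen. Among the 5 beta cell hormones and markers, Iapp rose by a log2 fold change of 1.25 ± 0.12, Mafa (-3.19 ± 0.34) and Ucn3 fell, and Ins1 and Ins2 did not pass, with the same counts adjusted over the list alone. The set test of the beta cell hormones gave an adjusted p of 0.0353 by camera, and adjusted p = 0.612 with an estimated correlation. The call ended without db/db 1 (adjusted p = 0.114, the highest over 1 library left out, the lowest being 0.0039).

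Of 15 tested progenitor and dedifferentiation genes, 10 rose, 1 fell and 4 did not pass, against 11 and 2 adjusted over the list alone. Aldh1a3 (7.68 ± 0.19, adjusted p = 2.04e-10) and Serpina7, which encodes thyroxine-binding globulin (5.71 ± 0.19, adjusted p = 1.22e-08), rose. Camera gave this list an adjusted p of 4.01e-13, and adjusted p = 0.197 with an estimated correlation. The count of risen progenitor and dedifferentiation genes was 7 without db/db 1 and 6 with acinar content as a covariate. Genes of the unfolded protein response, which relieves stress in the endoplasmic reticulum, moved upward, with 22 of 33 higher and 0 lower, also adjusted over the list alone (camera adjusted p = 1.25e-07, and adjusted p = 0.592 with an estimated correlation). Derl3 (1.77 ± 0.11) and Sel1l (1.09 ± 0.09), which act in the removal of misfolded proteins, rose. Of 25 genes of cholesterol biosynthesis, 16 fell and 0 rose, against 17 and 1 adjusted over the list alone. Msmo1, an enzyme of the pathway, fell by 1.08 ± 0.09. The adjusted p of cholesterol biosynthesis was 2.15e-07 by camera, and adjusted p = 0.197 with an estimated correlation. Leaving out db/db 1, 23 unfolded protein response genes rose, and 16 of cholesterol biosynthesis fell.

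Secretory granule genes went both ways. In the list of exocytosis machinery 9 of 25 members rose and 7 fell, against 10 and 7 adjusted over the list alone, and camera gave an adjusted p of 0.212. Chgb (2.17 ± 0.11) and Scg3 (1.43 ± 0.09), granins of secretory granules, rose, and Sytl4 (-2.39 ± 0.22) and Cadps (-0.60 ± 0.08) fell. Immediate early genes also divided, with 7 of 28 higher and 11 lower (8 and 11 adjusted over the list alone; camera adjusted p = 0.0595, from 6.77e-04 to 0.144 with a library left out, called without WT 1 or WT 2). Dusp6 (1.81 ± 0.13) and Klf6 (1.27 ± 0.11) rose, while Npas4 fell by 4.72 ± 0.13 and Arc fell by 2.78 ± 0.12. Of 31 genes of cell cycle and mitosis, 19 rose and 2 fell, against 25 and 2 adjusted over the list alone. The proliferation marker Mki67 (1.66 ± 0.18) and Rrm2 (1.61 ± 0.24) rose, and Ccnd2 (-1.56 ± 0.12) and Pcna (-0.50 ± 0.11) fell. The adjusted p of cell cycle and mitosis was 7.60e-04 by camera, and adjusted p = 0.612 with an estimated correlation. With acinar content as a covariate 3 of the cell cycle and mitosis genes rose, with the Y-linked counts as a covariate 7 did, and without db/db 1 the count was 18.

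Markers of some other cell types also rose. Of 34 tested acinar genes, 22 rose and 0 fell (27 and 0 adjusted over the list alone), with a median log2 fold change of 1.88. The trypsinogen genes Prss1 (11.02 ± 1.02) and Prss3 (9.24 ± 0.96) had the smallest adjusted p among them (2.87e-04 and 4.94e-04), and reads may be divided among near-identical trypsinogen copies, so their values are uncertain. In db/db, Prss1 stood at 2280, 511 and 622 CPM and Prss3 at 1382, 295 and 398 CPM, highest in db/db 1. Their WT means were 0.531 and 1.13 CPM, so depth limits the size of these fold changes. In the extracellular matrix list 26 of 35 members rose and 0 fell, also adjusted over the list alone, including Thbs1 (1.53 ± 0.12) and Col4a2 (0.75 ± 0.10). Of 22 markers of stellate cells, fibroblasts and pericytes, 13 rose and 0 fell (14 and 0 adjusted over the list alone), including Rgs5 (1.31 ± 0.11) and Notch3 (1.22 ± 0.16). Among 19 duct markers 11 rose and 0 fell, also adjusted over the list alone, including Cldn4 (1.10 ± 0.09) and Krt7 (0.90 ± 0.09). Camera gave adjusted p values of 3.15e-06 (acinar), 3.15e-06 (extracellular matrix), 3.39e-05 (stellate, fibroblast and pericyte) and 6.55e-04 (duct). These calls were lost, at adjusted p = 0.686, 0.641, 0.641 and 0.592 with an estimated correlation. Alpha cell markers mostly fell, 10 of 15 against 3 that rose, also adjusted over the list alone, without a camera call (adjusted p = 0.411, from 0.0344 to 0.862 with a library left out, called without WT 2). Slc7a2 (-1.21 ± 0.13) and Dpp10 (-1.38 ± 0.20) fell, while Gc (3.47 ± 0.11) and Slc38a5 (2.01 ± 0.25) rose. Camera made no call for endothelium (12 of 25 higher and 3 lower, adjusted p = 0.0644, from 0.0107 to 0.165 with a library left out), macrophages (7 of 27 and 0, adjusted p = 0.0644, from 0.00231 to 0.739), erythrocytes (1 of 7 and 0, adjusted p = 0.204, from 0.00769 to 0.381), delta and PP cells (2 of 14 and 3, adjusted p = 0.567), Schwann cells and neurons (3 of 17 and 1, adjusted p = 0.714) or lymphocytes (16 tested, adjusted p = 0.713). Without db/db 1, 13 acinar, 26 extracellular matrix, 12 stellate, fibroblast and pericyte, and 10 duct genes rose.

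With acinar content as a covariate, 1972 genes changed between db/db and WT, the calls of Slc2a2, Mafa and Gcg among others ended, and 1 extracellular matrix gene and 1 stellate, fibroblast and pericyte marker rose. This covariate lay between 8.26 and 9.60 log2 CPM in db/db and between 6.09 and 8.17 in the other libraries. An effect of acinar content thus cannot be told apart from one of genotype in the calls lost with it. The count of changed genes was 3719 with the Y-linked counts as a covariate, 4425 with the letter that opens each sample title as a covariate, and 1809 when tested against a 1.5-fold change. With library totals alone as the scale, all genes shifted by a median of -0.22 and the split became 2176 higher and 5317 lower, and with a transcript length correction it was 2842 and 4229. Without db/db 1 the count was 6583.

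**Figure D3:**
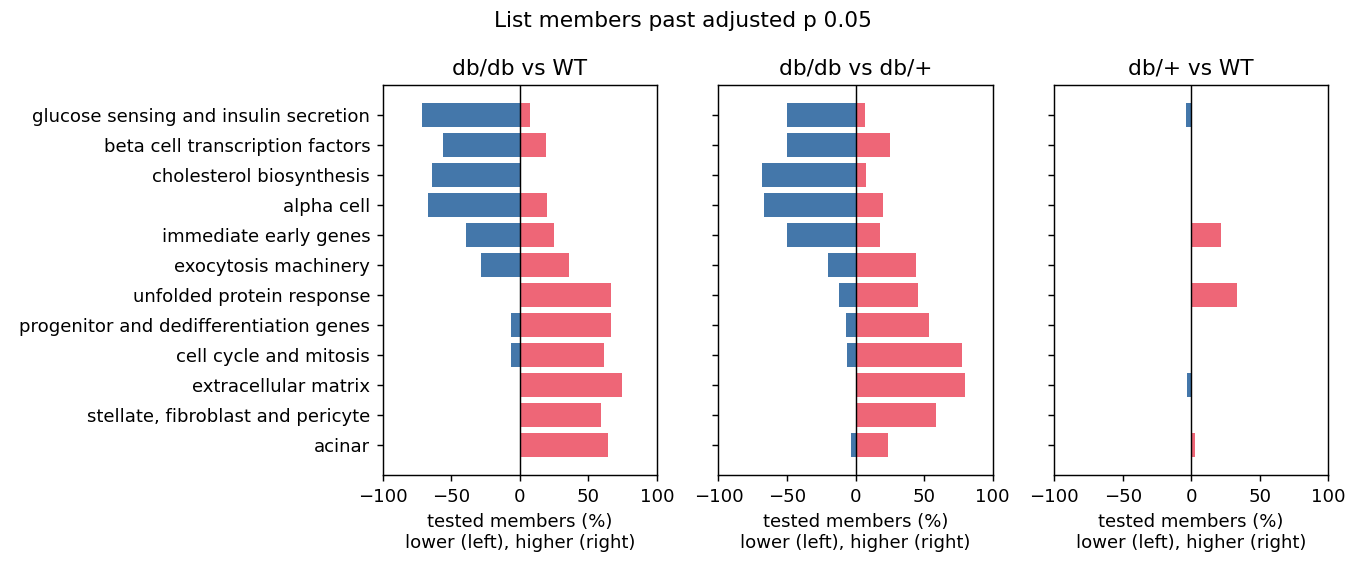
Share of tested members of 12 gene lists that were higher (red, right) or lower (blue, left) at adjusted p 0.05 over all genes, in percent, for each comparison. In db/db against WT, 20 of 28 genes of glucose sensing and insulin secretion are lower and 26 of 35 extracellular matrix genes are higher.

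The comparison of db/db with db/+ islets sets the mutant homozygotes against heterozygotes of the same strain label. Every db/+ library held Y-linked counts with almost no Xist, while db/db 2 and db/db 3 held Xist with almost no Y-linked counts. Only db/db 1 held both. Sex makeup thus largely followed genotype, and from this comparison alone an effect of sex cannot be told apart from one of genotype. Slc2a2 fell from 1260 ± 57.2 to 157 ± 75.5 CPM and Slc30a8 fell by 2.44 ± 0.18 on the log2 scale, both again chosen after their values were seen. Mafa stood at 14.1 ± 4.19 CPM in db/db and 128 ± 31.0 in db/+ (-3.16 ± 0.34, adjusted p = 3.69e-04), and Aldh1a3 at 496 ± 91.3 and 2.46 ± 0.244 CPM (7.64 ± 0.18, adjusted p = 2.83e-10). Iapp rose by a log2 fold change of 1.10 ± 0.12, Gcg fell by 1.03 ± 0.19, and Sst, the somatostatin gene, was lower by 0.48 ± 0.11 (adjusted p = 0.00356). Against WT, Sst in db/db did not pass (0.03 ± 0.11, adjusted p = 0.825), so this is not shown to be a fall from WT levels. Ins1 (-0.52 ± 0.29, adjusted p = 0.197), Ins2 (0.03 ± 0.14, adjusted p = 0.872), Ppy (-0.31 ± 0.14, adjusted p = 0.0908, from 0.0393 to 0.337 with a library left out) and Lepr (0.88 ± 0.64, adjusted p = 0.309) did not pass.

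In this comparison 6773 genes changed, 3459 higher and 3314 lower in db/db, 1438 and 679 of them by at least 2-fold. The 10 highest fold changes by the same rule were those of Prss1, Xist, Lars2, Prss3, Csn3, Cck, Aldh1a3, Bcat1, Ros1 and Slc5a10. Lars2 stood at 16002, 8292 and 10.6 CPM in db/db against 7.17 to 9.54 CPM in db/+, so db/db 3 hardly differed from db/+. Slc5a10, a sugar transporter gene, stood at 14.7 ± 5.68 CPM in db/db against a mean of 0.164 CPM in db/+, and Csn3, Bcat1 and Ros1 had db/+ means of 0.0269, 0.138 and 0.164 CPM. Cck had a db/+ mean of 0.249 CPM. The lowest were Kcnj12 (-5.85), Cox6a2 (-5.76), Trpm5 (-5.18), T2 (-4.98), Npas4 (-4.79), Cdh7 (-3.64), Tdrd6 (-3.60), Fam151a (-3.60), Kcng3 (-3.34) and Nnat (-3.19). The calls of Xist and Lars2 ended without db/+ 1, db/+ 2 or db/+ 3, with adjusted p up to 0.0626 and 0.0708 and down to 2.19e-04 and 2.99e-06 over the left-out libraries.

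In the list of glucose sensing and insulin secretion 14 of 28 members fell and 2 rose, against 15 and 2 adjusted over the list alone (camera adjusted p = 1.09e-12, and adjusted p = 0.286 with an estimated correlation). Gipr (-1.89 ± 0.09) and Ucn3 (-1.82 ± 0.10) fell, and Syt7 (0.43 ± 0.09) and Cpe (0.32 ± 0.10) rose. Of 16 beta cell transcription factors, 8 fell and 4 rose, also adjusted over the list alone, with Neurod1 (-1.02 ± 0.09) and Pdx1 (-0.87 ± 0.08) lower and Rfx6 (0.83 ± 0.08) and Bach2 (2.13 ± 0.22) higher. Camera gave the beta cell transcription factors an adjusted p of 0.0248, and adjusted p = 0.541 with an estimated correlation. That call ended without db/db 1 (adjusted p = 0.124, the highest over 1 library left out, the lowest being 0.00467). Of 15 progenitor and dedifferentiation genes, 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 1.09e-12, and adjusted p = 0.273 with an estimated correlation), with Bambi (2.04 ± 0.10) higher. The Cpe call ended without db/+ 2, db/+ 3, db/db 2 or db/db 3 (adjusted p from 0.00211 to 0.0856 over the left-out libraries). Leaving out db/db 1, 14 genes of glucose sensing and insulin secretion fell, and 7 progenitor and dedifferentiation genes rose.

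The unfolded protein response list had 15 of 33 members higher and 4 lower, against 16 and 5 adjusted over the list alone. Ern1, a sensor of unfolded proteins (0.75 ± 0.08), and Pdia6 (0.97 ± 0.11) rose, and Ppp1r15a (-0.48 ± 0.08) and the chaperone gene Calr (-0.49 ± 0.09) were lower than in db/+. Ppp1r15a was at 170 to 217 CPM in db/db, 165 to 171 CPM in WT and 261 to 272 CPM in db/+. Calr was at 1111 to 1331 CPM in db/db, 1039 to 1164 CPM in WT and 1627 to 1768 CPM in db/+. For Ppp1r15a and Calr the difference from db/+ is thus not shown to be a fall from WT levels. Camera gave the unfolded protein response an adjusted p of 0.0247, and adjusted p = 0.718 with an estimated correlation. The call ended without db/db 3 (adjusted p = 0.0569, the lowest over 1 library left out being 0.0115) and with the Y-linked counts as a covariate. In the extracellular matrix list 28 of 35 members rose and 0 fell (31 and 0 adjusted over the list alone), with Thbs1 (1.72 ± 0.12) and Col4a2 (1.06 ± 0.10) among them. Camera gave extracellular matrix an adjusted p of 3.75e-08, and adjusted p = 0.541 with an estimated correlation. It also called the markers of stellate cells, fibroblasts and pericytes (13 of 22 higher, 0 lower), endothelium (14 of 25 and 2), duct (10 of 19 and 2) and macrophages (10 of 27 and 0) higher, at adjusted p = 3.05e-06, 0.0163, 0.00885 and 0.0338, and at adjusted p = 0.560, 0.718, 0.541 and 0.810 with an estimated correlation. The macrophage call ended without db/db 1 (adjusted p = 0.544, the lowest over 1 library left out being 0.00102). Of 25 genes of cholesterol biosynthesis, 17 fell and 2 rose (18 and 2 adjusted over the list alone), with Msmo1 (-1.24 ± 0.09) lower and Dhcr7 (0.59 ± 0.15) and Ebp (0.46 ± 0.14) higher. The adjusted p of cholesterol biosynthesis was 2.85e-07 by camera, and adjusted p = 0.273 with an estimated correlation. The Ebp call ended without db/+ 2 or db/db 3 (adjusted p from 0.0113 to 0.124 over the left-out libraries). With library totals alone as the scale, 11 unfolded protein response genes rose and 8 fell.

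Interferon-stimulated genes were lower in db/db than in db/+, with 14 of 28 fallen and 0 risen, also adjusted over the list alone, including Ifit1 (-1.91 ± 0.22) and Irf1 (-0.84 ± 0.12). Camera gave them an adjusted p of 0.00382, and adjusted p = 0.541 with an estimated correlation. In db/db against WT the same list had 6 of 28 members lower and 3 higher, with no camera call (adjusted p = 0.229). Camera called it higher in db/+ than in WT (adjusted p = 1.82e-05, and adjusted p = 0.400 with an estimated correlation). The difference from db/+ is thus not shown to be a fall from WT levels. Immediate early genes had 14 of 28 members lower and 5 higher (15 and 5 adjusted over the list alone), with Npas4 and Arc (-2.58 ± 0.12) lower and Dusp6 (1.66 ± 0.13) and Ier3 (0.82 ± 0.18) higher. Their adjusted p was 9.52e-05 by camera, and adjusted p = 0.541 with an estimated correlation. With the Y-linked counts as a covariate 2 of the interferon-stimulated genes fell, 3 of the immediate early genes fell, and the camera calls of both lists in db/db against db/+ ended. Among acinar genes, 8 of 34 were higher and 1 lower (7 and 1 adjusted over the list alone), with no camera call (adjusted p = 0.0665, from 0.00101 to 0.369 with a library left out, called without db/+ 3 or any one db/db library). Prss1 (11.06 ± 1.02) and Prss3 (8.88 ± 0.93) rose, and the amylase gene Amy2a5 (-0.97 ± 0.30, adjusted p = 0.0206) was lower than in db/+. Amy2a5 was at 5.21, 5.33 and 3.88 CPM in db/db and 2.44 to 4.28 CPM in WT, so no fall from WT levels is shown. The Amy2a5 call ended without db/+ 3 or db/db 3 (adjusted p from 0.00544 to 0.118 over the left-out libraries).

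The count of changed genes between db/db and db/+ was 4437 with acinar content as a covariate, 1914 with the Y-linked counts, 2033 with the title letter and 1663 when tested against a 1.5-fold change. The title letter is G in every db/+ and H in every db/db title, so the title letter as a covariate separates this comparison only through the WT libraries. The calls of Gcg and Sst ended when tested against a 1.5-fold change, those of Sst, Prss1, Prss3 and Cck with the title letter, those of Iapp and Mafa with the Y-linked counts, and that of Sst also with acinar content. With library totals alone the split was 2011 higher and 5265 lower (median shift -0.23), and with the length correction 2856 and 4168. Without db/db 1 the count was 6142.

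Both db/db comparisons called 5289 genes in the same direction, 2775 higher and 2514 lower, and 9 in opposite directions. Independent lists of the same sizes would share 754 higher and 659 lower genes, but the 2 comparisons are not independent because they use the same db/db libraries. In 20 simulations of unchanged groups sharing the db/db libraries, the median overlap was 0 and the highest 1. These simulations hold no changed genes, so they do not give the overlap to set against the observed one. How much of the overlap comes from the shared db/db libraries was not measured. The shared count was 1301 against a 1.5-fold change, 1928 with the title letter, 1817 with acinar content and 1819 with the Y-linked counts as covariates, and 4896 without db/db 1.

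**Figure D4:**
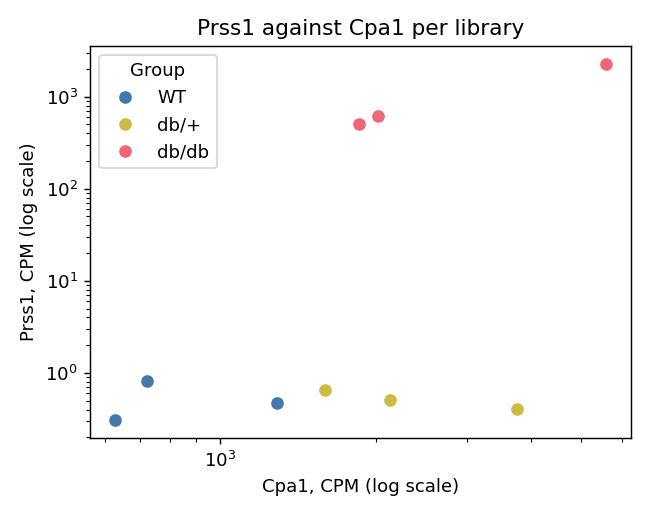
Prss1 against Cpa1 in each library, both in CPM on log axes. Prss1 stays below 1 CPM in the 6 WT and db/+ libraries whatever their Cpa1 level, and lies between 511 and 2280 CPM in the 3 db/db libraries.

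The comparison of db/+ with WT islets asks whether a single db allele goes with a change. Islet hormone genes differed little, and Sst alone among those named beforehand passed the test, rising from 1046 ± 39.7 to 1493 ± 152 CPM (0.51 ± 0.11, adjusted p = 0.0430). Ins1 (0.05 ± 0.29, adjusted p = 0.965), Ins2 (0.00 ± 0.14, adjusted p = 0.996), Iapp (0.15 ± 0.12, adjusted p = 0.607), Gcg (0.22 ± 0.19, adjusted p = 0.648) and Ppy (-0.04 ± 0.14, adjusted p = 0.928) did not pass. Ddit3, a transcription factor gene of the stress response, rose from 90.4 ± 14.2 to 249 ± 43.5 CPM (1.46 ± 0.21, adjusted p = 0.0362).

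A total of 240 genes changed, 102 higher and 138 lower in db/+, of which 9 and 4 by at least 2-fold. Among the highest fold changes were those of Ddit3, H2-K2, annotated as a transcribed pseudogene (1.29 ± 0.20), Rbm15b (1.19 ± 0.17) and the NF-kappaB inhibitor gene Nfkbia (1.01 ± 0.14). The 5 lowest were those of Muc4 (-1.17 ± 0.19), the basement membrane gene Hspg2 (-1.05 ± 0.17), the presynaptic gene Pclo (-0.97 ± 0.18), Dchs1 (-0.91 ± 0.19) and Prr12 (-0.89 ± 0.17).

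Of 33 genes of the unfolded protein response, 11 rose and 0 fell in db/+, against 17 and 1 adjusted over the list alone. Derl3 (0.96 ± 0.10, adjusted p = 0.00253) and Ppp1r15a (0.68 ± 0.08, adjusted p = 0.00285) had the smallest adjusted p. Camera gave the unfolded protein response an adjusted p of 3.61e-15, and adjusted p = 0.400 with an estimated correlation. Among 28 immediate early genes 6 rose and 0 fell (9 and 0 adjusted over the list alone), including Klf6 (0.88 ± 0.11) and Jun (0.69 ± 0.11), with an adjusted p of 1.51e-06 by camera, and adjusted p = 0.400 with an estimated correlation. Among 28 interferon-stimulated genes 3 rose and 0 fell (5 and 0 adjusted over the list alone), including the class I histocompatibility genes H2-D1 (0.52 ± 0.07) and H2-K1 (0.57 ± 0.09), whose similar sequences make their counts uncertain. Camera gave interferon-stimulated genes an adjusted p of 1.82e-05, and adjusted p = 0.400 with an estimated correlation. Acinar genes had a median log2 fold change of 1.39, with 1 of 34 higher and 0 lower, also adjusted over the list alone, the risen one being Amy2a5 (1.47 ± 0.30, adjusted p = 0.0414). The adjusted p of the acinar list was 4.59e-15 by camera, and adjusted p = 0.544 with an estimated correlation. With the Y-linked counts as a covariate 4 unfolded protein response genes, 1 of the immediate early genes, 0 interferon-stimulated genes and 0 acinar genes were higher.

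The size of this difference depended on single libraries and on the test. Changed genes numbered 44 without WT 3, 23 without db/+ 1, 27 without db/+ 2, 58 without db/+ 3, 430 without db/db 1, 79 without db/db 2 and 106 without db/db 3. The count was 640 with DESeq2, 67 higher and 52 lower with limma-voom, 46 without robust dispersion estimates, 27 with the Y-linked counts, 45 with the title letter and 125 with acinar content as covariates, 47 with the length correction, 768 without a low-count filter, and 0 when tested by edgeR against a 1.5-fold change, where 209 genes had an unadjusted p under 0.05. Of the 18 named calls, 14 ended with at least 1 library left out, and each of the 9 libraries ended at least 1. Their highest adjusted p over the left-out libraries was 0.201 for Sst, 0.136 for Ddit3, 0.0625 for H2-K2, 0.103 for Rbm15b, 0.0601 for Nfkbia, 0.174 for Muc4, 0.171 for Hspg2, 0.207 for Pclo, 0.193 for Dchs1, 0.174 for Prr12, 0.0553 for H2-K1, 0.103 for Jun and 0.154 for Amy2a5. Derl3, Ppp1r15a, Klf6 and H2-D1 stayed past the threshold with every library left out. The lists numbered 10 without WT 1 and 11 without WT 3, against 6 with all libraries.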

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

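Covariates of summed Y-linked counts, removal of ribosomal RNA genes and the transcript length correction were chosen after seeing the data; the other settings were fixed before. The cause of the differences given here was not tested unless stated. Of 3716 alternative log2 fold changes of 149 pairs of a named gene and a comparison, 3422 kept direction and side of the threshold, 233 fell short of the threshold, 12 newly passed it (Ppy, lower in both db/db comparisons), and 49 changed sign. All 49 sign changes were in genes past the threshold neither as reported nor under that setting. Of the named calls, 17 in db/db against WT, 20 in db/db against db/+ and 18 in db/+ against WT ended under at least 1 setting, and 1, 5 and 14 of these with a library left out. Depth limits the size of a fold change where a group holds almost no reads, as for Cck, Gast, Csn3, Ros1, Reg3g, Bcat1 and Slc5a10, so CPM are given for these.

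Genes changed in db/db against WT numbered 1809 when tested against a 1.5-fold change, 4425 with the title letter, 1972 with acinar content and 3719 with Y-linked counts as covariates, and 5774 to 7004 with each library left out. For db/db against db/+ the same settings gave 1663, 2033, 4437 and 1914, and 5441 to 6880 with each library left out. For genes called in both they gave 1301, 1928, 1817 and 1819, and 4376 to 5055. For db/+ against WT the count was 768 without a low-count filter, where more genes are tested, 640 with DESeq2, 67 higher and 52 lower (1.2e+02 in all) with limma-voom, 46 without robust dispersion, 45 with the title letter, 125 with acinar content and 27 with Y-linked counts as covariates, and 47 with the length correction. It was 0 in edgeR's test against a 1.5-fold change, with 209 genes at an unadjusted p under 0.05, and 23 to 430 with each library left out. Camera with an estimated correlation called 0 lists in db/db against WT, 0 in db/db against db/+ and 0 in db/+ against WT, with 3, 3 and 2 lists at an unadjusted p under 0.05, where the preset correlation gave 16, 20 and 6 and fry 20, 22 and 1. The lists changed in db/+ against WT numbered 12 with Y-linked counts as a covariate and 5 to 11 with each library left out; 14 to 20 and 17 to 21 were called in db/db against WT and against db/+.

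Log2 fold changes that changed sign are given by setting. With library totals only, they were -0.17 for Ins2 and -0.18 for Sst in db/db against WT, and -0.19 for Ins2 in db/db against db/+. Without a low-count filter, Ins2 was at -0.0059 and Sst at -0.0072 in db/db against WT, and Ins2 at -0.012 in db/+ against WT. DESeq2 gave -6.9e-04 for Ins2 in db/+ against WT. The title letter as a covariate gave Ins2 -0.048 in db/db against WT, and Ins2 -0.094 and Ppy 0.10 in db/db against db/+. Acinar content as a covariate gave Lepr -0.91 and Ins1 0.87 in db/db against WT, Lepr -0.27 and Ins1 0.069 in db/db against db/+, and Lepr -0.64 and Ppy 0.057 in db/+ against WT. Y-linked counts as a covariate gave Sst -0.28 in db/db against WT, and Lepr -1.02 and Ins2 -0.028 in db/+ against WT. The length correction gave Ins2 -0.25 and Sst -0.26 in db/db against WT, Ins2 -0.18 in db/db against db/+, and Ins1 -0.039 and Ins2 -0.076 in db/+ against WT. In db/+ against WT limma-voom gave Lepr -0.0062, and Ins2 was at -0.0030 with DESeq2 size factors, -0.0035 with upper-quartile factors, -0.013 with only the 2 groups fitted, -0.0041 without acinar genes and -0.0060 without ribosomal RNA genes. With each library left out, the ranges in db/db against WT were -0.13 to 0.17 for Ins2 and -0.032 to 0.14 for Sst. In db/db against db/+ they were -0.11 to 1.54 for Lepr and -0.031 to 0.12 for Ins2. In db/+ against WT they were -0.54 to 0.46 for Lepr, -0.12 to 0.15 for Ins1, -0.16 to 0.14 for Ins2, -0.0048 to 0.39 for Gcg and -0.18 to 0.072 for Ppy.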

Other observations

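The tests of the share of beta cells, of acinar tissue, of reads shared between trypsinogen copies and of a trypsinogen haplotype, and the group-level test of sex makeup, were chosen after their results or related values were seen; the length test was devised after long transcripts were seen among the lower genes, with a first criterion written before its value and tightened afterwards.

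Other gene groups also differed between db/db and WT islets. Of 38 cytosolic ribosomal proteins, 22 rose and 5 fell (23 and 6 adjusted over the list alone), with Rplp0 (1.15 ± 0.08) and Rps3 (0.90 ± 0.07) higher and Rpl3 (-1.20 ± 0.19) and Rps19 (-0.87 ± 0.16) lower. In WT, Rpl3 stood at only 16.6 to 21.1 CPM and Rps19 at 12.4 to 14.4 CPM, against 137 to 142 CPM for Rplp0. How reads that match several places were counted is not known, so such low values are uncertain. Nuclear genes of oxidative phosphorylation had 29 of 58 members higher and 2 lower (30 and 2 adjusted over the list alone), with Ndufa1 (2.03 ± 0.18) and Uqcrh (0.91 ± 0.09) higher and Sdha (-0.35 ± 0.08) and Cycs (-0.89 ± 0.23) lower. Camera gave these lists adjusted p values of 3.57e-05 and 3.55e-04, and adjusted p = 0.592 and 0.697 with an estimated correlation. On the scale of library totals, 10 genes of the list oxidative phosphorylation, nuclear genes were higher and 5 lower, and the camera call of that list ended with the length correction (adjusted p = 0.0661, the lowest over its alternatives being 2.94e-05). Among 24 genes normally kept low in beta cells, 10 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 0.00266 by camera, and adjusted p = 0.697 with an estimated correlation). Of 23 cytokines and chemokines, 12 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.00700 by camera, and adjusted p = 0.612 with an estimated correlation). Fatty acid synthesis genes had 4 of 20 higher and 8 lower (adjusted p = 0.0344 by camera, from 0.014 to 0.0514 with a library left out, and adjusted p = 0.592 with an estimated correlation).

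In db/+ against WT, camera called antioxidant defence higher (adjusted p = 0.00923, from 0.00147 to 0.127 over its alternatives, ending with the Y-linked counts and with the length correction, and adjusted p = 0.400 with an estimated correlation), with Txnip (0.52 ± 0.09, adjusted p = 0.0251, and up to 0.146 with a library left out) as its 1 member past the threshold of 28. It called mitochondrially encoded genes lower (adjusted p = 0.00958, from 7.95e-05 to 0.0524 with a library left out, and adjusted p = 0.400 with an estimated correlation), with 0 of 8 members past the edgeR threshold.

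The lower level of glucose sensing and insulin secretion genes in db/db islets was set against sex makeup, acinar tissue and a smaller share of beta cells. The 20 lower members had a median log2 fold change of -0.07 (95% interval -0.16 to 0.03) in db/+ against WT. Sex makeup as the whole cause would need at least 0.81 there (db/+ libraries hold more Y-linked counts). Acinar tissue as the whole cause would need -0.56 or less (db/+ libraries hold more acinar counts). With acinar content as a covariate 10 members of the list glucose sensing and insulin secretion were lower in db/db than in WT. That covariate was itself higher in every db/db library than in any other. The intervals given here are over genes measured in the same libraries, which are not independent replicates. They leave out the spread between libraries. In a test of sex makeup whose prediction was written before its value, but that rests on a single library and excludes nothing alone, 1938 genes that separate Xist-only from Y-only libraries had a median relative response of 0.99 (0.97 to 1.01) in db/db 1 against WT 1 and WT 3, which hold both. A smaller share of beta cells with no other change would raise the markers of all other cells alike, but the median in db/db against WT was -0.47 (-0.81 to 0.03) for alpha, delta and PP cells and 0.80 (0.66 to 1.03) for the other types. A smaller share together with more of the other types could also set these medians apart and is not tested by them. The medians argue against sex makeup or acinar tissue as the whole cause. The group-level tests were chosen after related values were seen, and no spread between libraries stands beside them. For the share of beta cells, the medians argue only against a smaller share with no other change. With the title letter as a covariate 18 members were still lower, but its effect is set only by WT 3 against WT 1 and WT 2. A single library cannot argue against a batch behind the letter. Ins2 (0.04 ± 0.14), Iapp (1.25 ± 0.12) and Chgb (2.17 ± 0.11) did not fall, which a dilution of all islet cells alone would not give, while Gcg fell (-0.81 ± 0.19). Ins2, Iapp and Chgb were chosen after their values were seen, so they do not decide on a dilution. A batch, mixtures of these causes and a change within db/db beta cells stay open.

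Of 12 trypsinogen genes of a cluster on chromosome 6 (40948462 to 41525079), 7 near-silent ones summed to 2.44 to 3.88 CPM over the 6 WT and db/+ libraries and to 1677 to 7756 CPM over the 3 db/db ones. The median log2 fold change of these 7 exceeded that of 28 other acinar genes by 10.57 against db/+ (spread of the others 0.76). The 7 were picked from these same libraries for being near-silent in WT and db/+, so that excess was largely set by the choice. More acinar tissue alone still does not account for the rise of these 7. The 28 other genes summed to 39316 CPM in db/+ 3 and 22093 CPM in db/db 2, where the 7 summed to 3.67 and 1677 CPM. Ctrb1, chosen after its values were seen, was at 3139 CPM in db/+ 3, which had no such rise. Reads moved between near-identical copies, with all of them counted, would leave the summed trypsinogen count relative to other acinar genes equal, but it was 2.22 times as high in db/db (spread 0.26). How reads that match several copies were counted is not known, so a difference in which reads were counted stays open. Of 27 neighbouring genes, 5 changed in both db/db comparisons (18.5%, against 31.5% of all genes; exact binomial p = 0.212), which gives no sign of a haplotype over a wider stretch. A haplotype limited to the cluster, a difference in which reads were counted, or a change in acinar cells of db/db mice may each lie behind the rise. They cannot be told apart because the rise is in all db/db libraries and in no other.

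Genes lower in db/+ than in WT were long, with a median transcript length of 6858 bases against 3019 for all tested genes and 2528 for the higher ones. Across genes, which are not independent replicates, log2 fold change fell with length (Spearman rho -0.27), and after a per-library length correction 13 of the 138 lower calls stayed past the threshold. By the criterion written before the value was known, this fits a length trend as the cause. A further condition, that the fold shrink by more than 50%, was added after the result and was not met: the median log2 fold change of the lower calls went only from -0.53 (SE 0.109) to -0.43 (SE 0.112). For each library, the deviation of each gene's level from its mean over all 9 libraries was rank-correlated with length. That correlation was higher in every WT library (0.073 to 0.244) than in every db/+ library (-0.125 to -9.5e-04). A length trend may thus be the cause and cannot be told apart from a difference between the genotypes.

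With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 7018 genes for db/db against WT, 6773 for db/db against db/+ and 240 for db/+ against WT, as many as which only 1 split (the real one) gave in each case, and the highest other split gave 0 in each by edgeR. Every other split put libraries of both genotypes in each arm, where any genotype difference widens the spread within arms. Low counts from those splits were thus likely in advance and do not decide on the real grouping.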
